A study of Arabidopsis thaliana with 4 samples.

How the data were processed

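Total RNA from whole Arabidopsis thaliana seedlings of the Col-0 background was measured on 4 one-colour NimbleGen expression arrays labelled with the dye Cy3, per the labels. The comparison was between genotypes with 2 arrays each, the wild type and a line that carries the transgene 35S::JMJ30-HA, in which the strong 35S promoter of cauliflower mosaic virus drives an HA-tagged copy of the histone demethylase gene JMJ30. Plants were grown on soil at 22 °C with 16 hours of light and 8 hours of dark, and seedlings were harvested 13 days after germination, per the labels. The labels describe the arrays of each genotype as biological replicates and do not give the hour of harvest.

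The deposited values are normalized intensity values on a linear scale, 1 per transcript model, with 37118 models named by the locus code of the gene and a model number. The submitters' processing notes name RMA, which corrects background, normalizes between arrays and summarizes probes, without a version or settings. RMA output is commonly on the log2 scale, but the deposited intensity values reach 4400 and the lowest is 1.50, so they were taken as linear, and log2 was computed from them. No value was at or below 0, so no pseudocount was added. Median intensity per array lay between 25.6 and 26.6. The data used here hold neither a background measurement nor a detection call per probe set, and the number of probes behind a value is not given in the sources used here. The mean log2 values of all genes had 2 modes, at intensities of 4.27 and 193, with a valley between them at 12.9. A gene whose mean in both genotypes lay under this valley is called near background below, a description of its level and not a detection call. The number of arrays limits the precision of every value.

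Where a gene had several transcript models (3602 of 32627 genes, with up to 10 models), the model with the highest mean log2 value over all 4 arrays stood for it. Gene symbols came from the NCBI gene table of assembly TAIR10.1, in which 31993 of the 32627 locus codes (98.1%) were found. The array files name no genome build, so no coordinates are given, and the table served for names and for which genes neighbour each other.

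Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, genotype as the only term, two-sided) with Benjamini-Hochberg adjustment over 32627 genes, and a gene was called at an adjusted p below 0.05. Differences are log2 of the transgenic line minus log2 of the wild type, with the moderated standard error (SE), and intensities are means ± SD. Plots were drawn with matplotlib 3.10.9. Gene lists were tested with camera from limma, two-sided, at its preset inter-gene correlation of 0.01, with adjustment over the 18 lists. Calls adjusted over the list alone were counted too. The lists, the main test, the rule for named genes and most alternatives were fixed before the data were examined. The lists were floral repressors, floral promoters, developmental Polycomb target genes, morning and evening clock genes, the H3K27 and H3K4 methylation machinery, heat shock response, abscisic acid, cold and drought response, salicylic acid and pathogen defence, jasmonate and wound response, photosynthesis, light and elongation, LBD genes of callus formation, leaf senescence and sugar starvation, iron status, flavonoid and anthocyanin genes, and seed and root tissue markers. Of 284 entries, 279 were used. RVE6, JMJ13, HSP17.6C and HSP15.7 were left out because the reference table gave other names for their locus codes, and HSFB1 had no value.

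The rule for named genes was as follows. JMJ30, FLC, FT and SOC1 were always named. In each direction the 10 genes with the largest log2 difference among those called and with both arrays of one genotype above both of the other were to be named. Where fewer were called, the genes with the largest absolute moderated t filled the 10 and are given as values. In each list the members called, up to 6, were named, or the 2 with the largest absolute moderated t if none was called. Genes outside this rule are marked where they appear.

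Both genotypes carry the replicate numbers 1 and 2 in the labels. The series' design text speaks of independent sets that each hold both genotypes, which was read as saying that equal numbers belong to one set. The text does not say what a set shared, and another reading, of separate samples within each genotype, is possible. The values were checked for the pairing before the calls of the fits were compared. The deviations from the genotype means correlated at 0.42 across all genes and at 0.68 across the 18081 genes with a mean above the valley, where genes are not independent replicates. Arrays with the same number correlated at 0.989 and 0.990 on the log2 scale, and arrays of the same genotype at 0.982 and 0.983. Same-numbered arrays are therefore called set 1 and set 2, and the fit with the replicate number as a block is given where it changes a call. No pair of arrays shared more than 13 identical values among 37118, so no array was counted as a duplicate.

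The steps were tested on simulated data for the comparison of the transgenic line with the wild type, in 10 simulations of 32627 genes with 200 changed genes each. All changed genes were drawn from those above the valley, so recovery of genes near background was not simulated. Without the block, calls recovered 0% of genes changed by 1 on the log2 scale, 7.4% of those changed by 2, 80.8% by 3 and 96.4% by 5. With the block the shares were 0%, 71.8%, 98.2% and 100%. With the block and the 18081 genes above the valley they were 82%, 99.8%, 100% and 100%, with 8.43% false calls. A list of 18 genes above the valley, simulated independently and each shifted by -0.4, had a camera p under 0.05 in 10 of 10 simulations in each fit. That p was not adjusted over lists. Real lists hold correlated and dim members, so this share does not give the power for them.

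Alternatives fixed beforehand were the replicate block, leaving out each array in turn, quantile normalization again, centring on the array median, leaving out the dimmest genes (mean log2 value under 2.23, the lower quartile), eBayes with trend and robust settings, array weights, the mean of a gene's transcript models, log2(value + 16), other thresholds, an ordinary linear model, an estimated inter-gene correlation and fry in place of camera. Alternatives chosen after seeing the data were restriction to genes above the valley, alone and with the block, the block with an ordinary linear model or with an estimated correlation, and a variance prior fitted apart in 2 parts of the genome. With an estimated correlation camera refers its statistic to the residual degrees of freedom, 2 without the block and 1 with it. A list can then hardly be called whatever its correlation. A call lost there weighs neither for nor against the list, and it leaves the preset correlation unchecked. No data column was left out.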

Results

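Transcript levels were measured in whole 13-day-old seedlings of wild-type Arabidopsis and of a late-flowering line with the transgene 35S::JMJ30-HA, on 2 arrays per genotype. Each array gave a normalized intensity for 37118 transcript models of 32627 genes. The median intensity per array was 25.6 to 26.6 and the highest value per array 3347 to 4400. Between 18039 and 18151 genes per array lay above the valley of the intensity distribution. The design asks how expression differs between a line made to overexpress JMJ30 and its wild type.

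JMJ30 (AT3G20810), which encodes a jumonji-domain histone demethylase and is the gene placed under the 35S promoter, had an intensity of 636 ± 98.0 (SD, n = 2) in the wild type and 887 ± 235 (SD, n = 2) in the transgenic line. The single arrays read 705 and 567 in the wild type and 1054 and 721 in the transgenic line. The difference was 0.46 ± 0.27 (SE) on the log2 scale, 0.58 in set 1 and 0.35 in set 2. It did not pass the limma test (adjusted p = 1.0), and its 95% interval ran from -0.22 to 1.14 before adjustment. With the replicate block that interval ran from 0.0093 to 0.92, and the gene stayed uncalled (adjusted p = 0.829). In the wild type 97.4% of genes had a lower mean than JMJ30. The transcript models of the gene differed in direction. Model 3 read 0.40 higher in the transgenic line, whereas the dimmer model 2 read 47.7 and 52.9 in the wild type and 32.5 and 38.0 in the transgenic line, a log2 difference of -0.52. With the mean of all models the difference of JMJ30 was 0.12. Probe positions are not given in the sources used here, so it is not known whether these values include the transcript of the transgene. Both transgenic arrays lay above both wild-type arrays at JMJ30. On simulated data the comparison recovered 0% of genes changed by 1 on the log2 scale, 7.4% of those changed by 2 and 80.8% of those changed by 3, so the missing call leaves a small difference open and goes against a large one in what these probes read. Without single arrays the difference of JMJ30 ran from 0.19 (without transgenic replicate 1) to 0.74 (without transgenic replicate 2).

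FLC (AT5G10140), the MADS-box repressor of flowering, had an intensity of 12.7 ± 0.81 (SD, n = 2) in the wild type and 29.1 ± 5.22 (SD, n = 2) in the transgenic line, a 2.26-fold difference. The arrays read 13.3 and 12.2 against 25.4 and 32.7. The log2 difference was 1.18 ± 0.22 (SE), 0.93 in set 1 and 1.43 in set 2, with a 95% interval from 0.63 to 1.73 before adjustment. FLC lies in the part of the locus order where arrays spread more, and with a variance prior fitted there apart, chosen after seeing the data, the interval ran from 0.59 to 1.76. It did not pass the limma test over all genes (adjusted p = 1.0) or adjusted over the list alone among 20 floral repressors (adjusted p = 0.0526). The wild-type level lay at the valley, and models 2 and 3 of FLC, both near background, read -0.26 and -0.09. With the mean of all models the difference was 0.28, and with log2(value + 16) it was 0.64. FT (AT1G65480), the mobile floral signal, was near background, at 4.97 ± 1.39 in the wild type and 3.63 ± 0.43 in the transgenic line. SOC1 (AT2G45660), a floral integrator that FLC represses, read 99.2 ± 9.87 and 74.7 ± 18.9. The log2 differences were -0.43 ± 0.27 for FT and -0.43 ± 0.25 for SOC1, neither past the test (adjusted p = 1.0 for both).

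**Figure D1:**
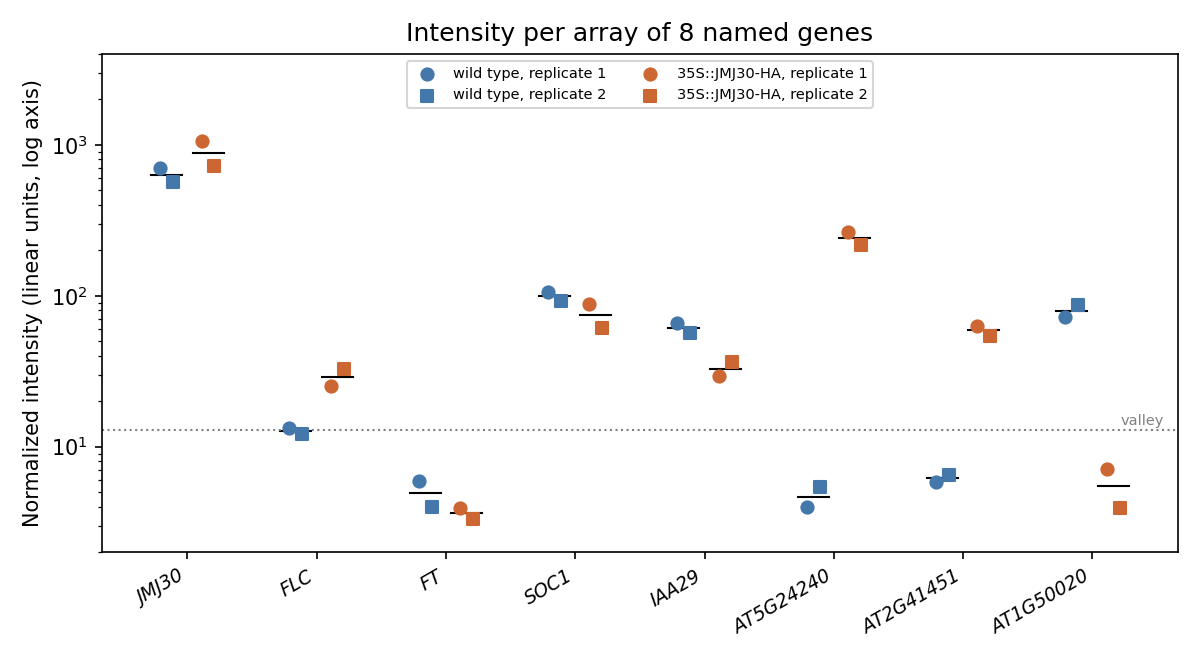
Normalized intensity (linear units on a log axis) of 8 named genes on each of the 4 arrays, with circles for replicate 1, squares for replicate 2 and bars for the arithmetic mean of each genotype. The dotted line is the valley at 12.9. AT5G24240 goes from 4.66 in the wild type to 240 in the transgenic line, while JMJ30 goes from 636 to 887.

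The 20 floral repressors split evenly, 10 higher and 10 lower in the transgenic line, with a median log2 difference of 0.0067 (camera adjusted p = 0.906). Besides FLC, the member with the largest moderated t was ATC, a relative of TFL1, near background at 6.31 and 4.23 (log2 difference -0.58 ± 0.18). Of the 20 floral promoters 7 were higher and 13 lower, with a median of -0.15 (adjusted p = 0.428). CO, which activates FT in long days, read 39.5 ± 5.44 and 53.7 ± 9.62, a log2 difference of 0.44 ± 0.23. Without single arrays the mean of the promoters ran from -0.27 to 0.056. These values carry the difference between the sets, because 1 set then holds a single genotype. AGL42 was near background in both genotypes, at 6.85 and 3.35. No member of either list was called over all genes or adjusted over the list alone.

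Across all genes, limma called 0 of 32627 at the threshold, with 974 genes (2.99%) at an unadjusted p under 0.05. An ordinary linear model also called 0, and eBayes with trend and robust settings called 1. With the replicate number as a block the count was again 0, with 1961 genes at an unadjusted p under 0.05. When the block was combined with a restriction to the 18081 genes above the valley, a setting chosen after seeing the data, 3 genes were called, 2 higher and 1 lower. In simulated data that setting gave 8.43% false calls.

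These 3 genes had the largest absolute moderated t of all genes. AT5G24240, of the phosphoinositide 4-kinase family, was near the lower mode in the wild type, at 4.66 ± 0.999 (SD, n = 2), and at 240 ± 31.5 (SD, n = 2) in the transgenic line. Its log2 difference was 5.70 ± 0.24 (SE), with an adjusted p of 0.0633 in the main comparison. The adjusted p was 0.00181 with trend and robust settings and 0.000956 with the block above the valley, and ran up to 0.471 over its alternatives. AT2G41451, a protein-coding gene without a symbol, read 6.18 ± 0.49 and 58.9 ± 6.51, a log2 difference of 3.25 ± 0.20. Its adjusted p was 0.208, and 0.00351 to 1.0 over its alternatives, the lowest with the block above the valley. AT1G50020 went the other way, at 79.3 ± 9.88 in the wild type and 5.50 ± 2.22 in the transgenic line. Its log2 difference was -3.90 ± 0.33, with an adjusted p of 0.682, and 0.0195 to 0.9999 over its alternatives, the lowest again with the block above the valley. With arrays under the valley of 12.9 taken at the valley, the differences were at least 18.5-fold, 4.54-fold and 6.12-fold. In set 1 and set 2 the log2 differences were 6.05 and 5.34 for AT5G24240, 3.44 and 3.06 for AT2G41451, and -3.35 and -4.46 for AT1G50020.

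None of the other genes that filled the 10 places per direction was called, and apart from FLC and AT4G31570 all were near background. Of the 20 genes in these places 13 lie in the part of the locus order with more spread, which holds 28.1% of nuclear genes. With the variance prior fitted apart for that part, 0 genes were called. AT4G31570 read 16.6 ± 4.24 and 6.29 ± 0.94, a log2 difference of -1.39 ± 0.26. Both of its transgenic arrays (6.96 and 5.62) lay under the valley, so the size of that difference is uncertain. RBE, a zinc-finger gene of petal development, read 7.61 and 2.89, and COPT3, of the copper transporter family, read 3.84 and 8.07. The other higher values belonged to AT5G24880, AT5G36659, AT2G10480, AT4G36925, AT2G10680 and AT5G44313, with log2 differences from 0.98 to 1.27. The other lower values belonged to AT4G31660, AT4G11770, AT5G38030, AT5G64735, AT5G44220, AT2G23400 and AT1G33500, with log2 differences from -1.20 to -0.997.

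Genes of light signalling and elongation growth leaned towards lower values in the transgenic line, 11 of 12 members, with a median log2 difference of -0.18. In both sets taken apart 6 of the 12 were lower and 0 higher, and the other 6 differed in sign between the sets. IAA29, an auxin-inducible gene of the Aux/IAA family, read 61.4 ± 6.99 and 32.9 ± 4.68, a log2 difference of -0.90 ± 0.21, -1.16 in set 1 and -0.64 in set 2. YUC8, which encodes an auxin biosynthesis enzyme, was near background at 8.82 and 5.54. The list was not called by camera (adjusted p = 0.0515). It was called as lower with the replicate block (adjusted p = 0.0223), but not with an estimated correlation (adjusted p = 0.967, and 0.954 with the block). The same list read higher in set 2 than in set 1 for 10 of 12 members, in both genotypes combined, with a median of 0.28. Without single arrays the mean of the list ran from -0.47 to -0.028, values that carry this difference between the sets.

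Of 18 heat shock genes 14 were lower and 4 higher in the transgenic line, with a median log2 difference of -0.25. In both sets taken apart 10 were lower and 2 higher. HSP21, a small heat shock protein of the plastid, read higher, at 3.21 and 6.17, and HSP17.6II read lower, at 5.26 and 3.33, both near background. HSP70 (AT3G12580), chosen after its values were seen, read 38.9 and 146 in the wild type and 26.1 and 104 in the transgenic line, in the order set 1 and set 2. The list was not called by camera (adjusted p = 0.248). It was called as lower with the replicate block (adjusted p = 0.0223), but not with an estimated correlation (adjusted p = 0.967, and 0.954 with the block). That correlation was 0.174 without the block, above the preset 0.01, in a fit that carries the difference between the sets. With the block it was -0.0065, an estimate from 1 residual degree of freedom. Neither value checks the preset, and the loss of the call weighs neither for nor against the list. Heat shock genes also differed between the sets, with 13 of 18 higher in set 2 and a median of 0.35. Without wild-type replicate 2 or without transgenic replicate 1 the mean genotype difference of the list turned to 0.06 and 0.07. The lowest mean without a single array was -0.51. These values carry the difference between the sets.

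**Figure D2:**
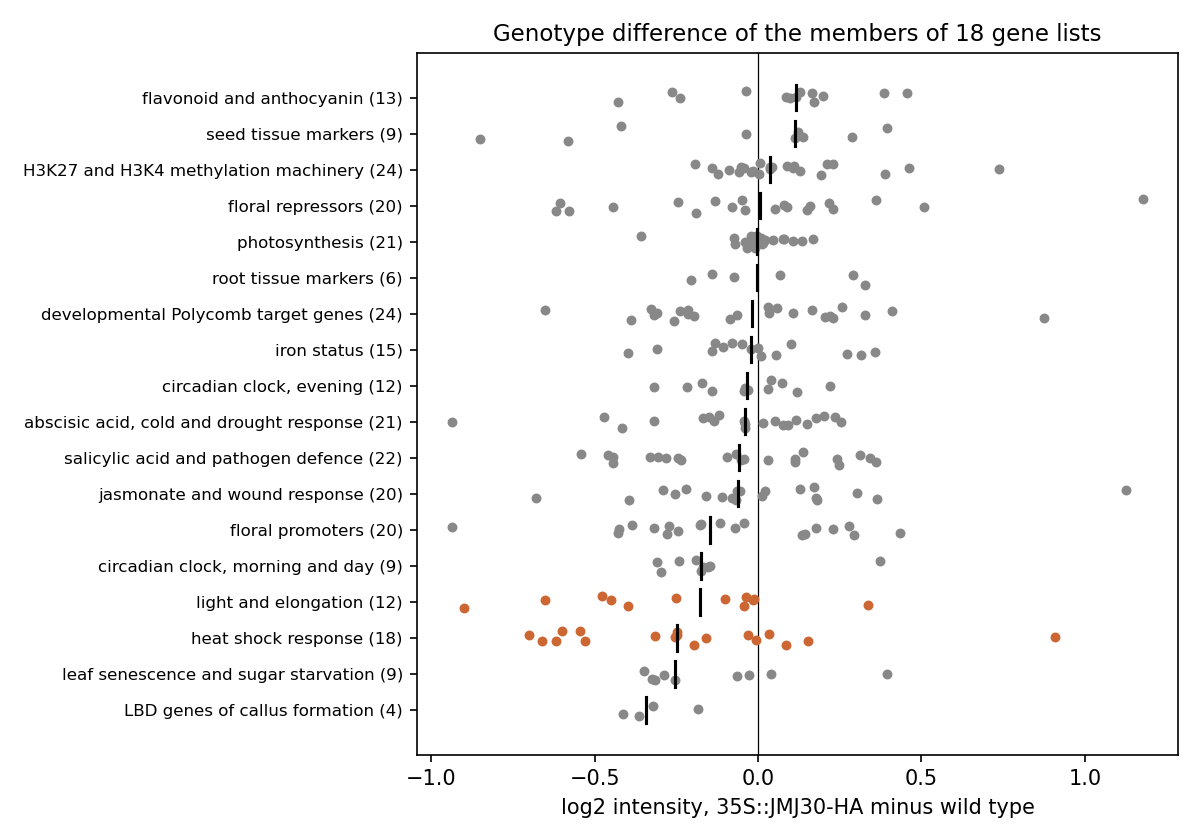
Log2 intensity difference between the transgenic line and the wild type for each measured member of 18 gene lists, with the number of members in parentheses and a bar at the list median. Orange marks the 2 lists called with the replicate block at the preset correlation, light and elongation (median -0.18) and heat shock response (median -0.25), neither of which the main comparison called. Neither was called with an estimated correlation (adjusted p = 0.954 with the block), a fit with 1 residual degree of freedom that can hardly call any list.

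The remaining lists were not called on all 4 arrays, with or without the replicate block. In the H3K27 and H3K4 methylation machinery 15 of 24 members were higher (median 0.04, adjusted p = 0.428), a list that includes JMJ30 itself. Its relative JMJ32 was near background at 6.87 and 11.7, and VIN3, which acts in vernalization, at 3.25 and 4.29. Developmental Polycomb target genes split 12 and 12 (median -0.02, adjusted p = 0.906), with SEP2 at 4.89 and 8.97 and PHE1 at 5.47 and 3.47, both near background. Of 9 morning clock genes 8 were lower (median -0.17, adjusted p = 0.782), with RVE4 at 245 and 220, and CCA1, the exception, at 13.3 and 17.01. Of 12 evening clock genes 7 were lower (median -0.03, adjusted p = 0.906), among them TOC1 at 690 and 618 and FKF1 at 481 and 380. Without transgenic replicate 1 TOC1 turned to 0.021, and without transgenic replicate 2 RVE4 turned to 0.0045. Between the sets, in both genotypes combined, the morning genes had a median of 0.56 and the evening genes one of 0.21, both higher in set 2. Without single arrays the mean of the morning list ran from -0.58 to 0.29, values that carry this difference between the sets.

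Stress and hormone lists had medians near 0. Of 21 abscisic acid, cold and drought genes 11 were lower (median -0.04, adjusted p = 0.863), with RD29A at 342 and 266 and NAC055 at 65.3 and 34.4. The sets disagreed on NAC055, with log2 differences of -2.05 in set 1 and 0.17 in set 2, and without transgenic replicate 1 RD29A turned to 0.075 and NAC055 moved from -0.94 to -0.37. Salicylic acid and defence genes were lower for 13 of 22 members (median -0.06, adjusted p = 0.695), with NIMIN1 and ALD1 near background. Jasmonate and wound genes were lower for 11 of 20 members (adjusted p = 0.906). Their median of -0.06 and the direction of the test differed in sign from their mean of 0.01. MYC2 read 448 and 361, with log2 differences of -0.59 in set 1 and 0.013 in set 2. PDF1.2, near background in both genotypes, read 5.604 and 3.69 in the wild type and 18.6 and 5.30 in the transgenic line, and its log2 difference of 1.13 was 0.22 without transgenic replicate 1. Iron genes were lower for 9 of 15 members (median -0.02, adjusted p = 0.906), with BHLH100 and BHLH039 near background. Flavonoid and anthocyanin genes were higher for 9 of 13 (median 0.11, adjusted p = 0.906), although FLS1 read 17.5 and 12.8, and PAP2 was near background. Between the sets the medians were 0.58 for the abscisic acid, cold and drought list, -0.57 for salicylic acid and defence, -1.05 for jasmonate and wound response and 0.19 for iron, as set 2 minus set 1. Leaving out 1 array leaves a set with 1 genotype, and the jasmonate list was then called each time, with means from -0.64 to 0.65. The abscisic acid list was called in the same way without any array but wild-type replicate 2 (means from -0.55 to 0.41). The salicylic acid list was called without wild-type replicate 2 or transgenic replicate 1 (lowest mean -0.44).

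Photosynthesis genes split 10 and 11 (median -0.0021, adjusted p = 0.906), with LHCA1, a light-harvesting protein gene of photosystem I, at 1704 ± 112 and 1334 ± 188 and CAB2 near background. All 4 LBD genes of callus formation were lower (median -0.34, adjusted p = 0.248), with LBD16 near background and LBD18 at 16.6 and 13.3, which turned to 0.15 without transgenic replicate 1. Without single arrays the mean of the LBD list ran from -0.61 to -0.027. These values carry the difference between the sets, since 3 of its 4 members were higher in set 2 (median 0.58). Of 9 senescence and sugar starvation genes 7 were lower (median -0.25, adjusted p = 0.491), among them SEN1 at 625 and 514 and SAG13 at 17.7 and 14.2. Seed markers were near background throughout, including CRA1 and SESA2, with 5 of 9 higher (median 0.11, mean -0.09, adjusted p = 0.906). Root markers split 3 and 3 (median -0.0033, mean 0.044, adjusted p = 0.906), with NRT2.1 and PRP3 near background. No member of any list was called over all genes or adjusted over the list alone.

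The arrays also separated by replicate number, and more widely than by genotype. The SD over all genes of the log2 difference was 0.41 between the sets and 0.27 between the genotypes, and 868 genes differed at least 2-fold between the sets against 112 between the genotypes. In the comparison of the sets, which was not planned, limma with both terms called 4 of 32627 genes, all lower in set 2, with 5044 at an unadjusted p under 0.05. TAT3, FAMT, PCC1 and AT3G22235 read 109, 267, 555 and 384 in wild-type replicate 1 and 3.98, 9.47, 12.1 and 22.4 in wild-type replicate 2. In the transgenic line they read 141, 218, 463 and 369 in replicate 1 and 4.66, 9.90, 15.1 and 24.8 in replicate 2.

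**Figure D3:**
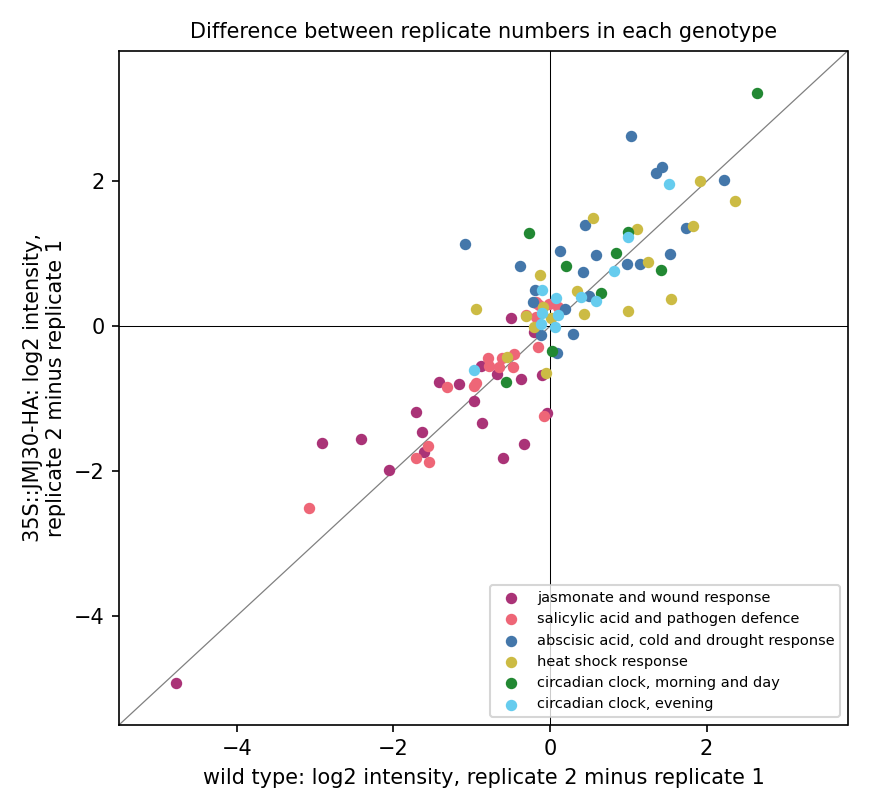
Log2 intensity of replicate 2 minus replicate 1 in the wild type (horizontal) and in the transgenic line (vertical) for the members of 6 gene lists, with the diagonal of equal difference. All 20 jasmonate and wound genes have a mean difference below 0, and 19 of 21 abscisic acid, cold and drought genes one above 0.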

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

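The alternatives that restrict genes to those above the valley, that combine the replicate block with another choice, or that fit the variance prior in 2 parts were chosen after seeing the data. The count of called genes was 0 in the main comparison and under all alternatives except 4. It was 1 with trend and robust settings, 1 at an adjusted p below 0.10 (AT5G24240 in both), 72 at an unadjusted p below 0.05 with a 2-fold difference (31 higher, 41 lower), and 3 with the replicate block above the valley. Without each array in turn it was 0 to 0. The replicate block alone gave 0 genes, and the pairing changed no call other than those of the 2 lists and 3 genes named here. JMJ30 kept its direction and stayed uncalled throughout, at 0.12 with the mean of models and 0.19 to 0.74 without each array in turn. FT (-0.72 to -0.14) and SOC1 (-0.69 to -0.17) did too. FLC (0.99 to 1.36) kept its direction and was uncalled at every adjusted p, but is among the 72 genes at an unadjusted p below 0.05 with a 2-fold difference. Of 58 named genes 31 moved by over 1.5 times without some array, none of them called in the main comparison. FT lies under both filters on dim genes and has no value there.

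No list was called in the main comparison, with array weights, trend, an estimated correlation with or without the block, fry, or genes above the valley. The count was 2 with the replicate block and 2 with the replicate block above the valley, where 15 lists could be tested (heat shock, adjusted p = 0.00101, and light and elongation, 0.0423). It was 1, light and elongation, with quantile normalization again, centring, the dimmest genes left out, the mean of models, and log2(value + 16), where its adjusted p was 0.0493, 0.0328, 0.0218, 0.033 and 0.0301. Over all its alternatives that adjusted p ran up to 0.994, with fry. The count of lists was 2 to 6 without each array in turn. Leaving out 1 array leaves one set in a single genotype, so these calls carry the difference between the sets: the mean of the jasmonate list ran from -0.64 to 0.65 and was called each time. With 3 arrays the lone array is assumed to vary like the other genotype.

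The other lists that changed direction without single arrays had means from -0.047 to 0.051 (floral repressors), -0.27 to 0.056 (floral promoters), -0.094 to 0.065 (Polycomb targets), -0.58 to 0.29 and -0.26 to 0.18 (morning and evening clock), -0.51 to 0.071 (heat shock), -0.55 to 0.41 (abscisic acid), -0.44 to 0.29 (salicylic acid), -0.047 to 0.047 (photosynthesis), -0.18 to 0.16 (iron), 0.032 to 0.097 (flavonoid genes, in the direction of the test only) and -0.13 to 0.21 (root markers). Among named genes RVE4 (-0.34 to 0.0045), TOC1 (-0.36 to 0.021), RD29A (-0.91 to 0.075), LBD18 (-0.98 to 0.15) and PRP3 (-0.54 to 0.13) did. Other settings turned the direction of the test for uncalled lists with means near 0, in some without a change in the sign of the mean. The mean of models gave -0.078 for floral repressors, 0.033 for jasmonate and 0.0065 for iron genes. Leaving out the dimmest genes gave 0.00060 for Polycomb targets and 0.014 for jasmonate genes. The block above the valley gave -0.011 for Polycomb targets and -0.027 for jasmonate genes, and the replicate block, with a preset or estimated correlation, 0.0055 for jasmonate genes. For these the cause was not tested. Genes near background carry little signal, which limits what the arrays show of FT and of 18 of 24 Polycomb targets.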

Other observations

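All comparisons and tests in this part were chosen after the results were seen, and for the 3 genes with an on or off pattern the test for array noise is the third tried, with the same reading from the earlier ones, and a test of the transgenic line was left out because it restated how these genes were chosen. The test of normalization is also the third tried, since in both earlier ones the normalization already done fixed the outcome. The test of time of day is the second, since the first only restated that clock genes differ between the sets. Set 1 and set 2, grouped by replicate number alone, differed in several lists of hormone and stress response genes. All 20 jasmonate and wound genes were lower in set 2, with a median log2 difference of -1.05 (camera with the replicate number and genotype as terms, adjusted p = 3.43e-15, and 0.569 with an estimated correlation). The values with an estimated correlation in this part rest on 1 residual degree of freedom, so they weigh neither for nor against a list. For the jasmonate list that correlation was -0.042, equal to that of the floral repressors, a list of the same size. It therefore does not check the preset 0.01. In the fit with genotype alone it was 0.85, which carries the difference between the sets. The adjusted p at the preset correlation thus treats genes that may vary together as nearly independent. TAT3 was the member called over all genes, and 16 members passed when adjusted over the list alone. Its values were 28.8-fold lower in set 2, but both arrays there (3.98 and 4.66) lay under the valley, so the size of that fold is uncertain. JAZ10, a repressor of jasmonate signalling, read 142 and 26.6 in replicates 1 and 2 of the wild type and 88.6 and 30.1 in the transgenic line. AOC1, an enzyme of jasmonate synthesis, read 370 and 89.2 in the wild type and 466 and 117 in the transgenic line. Of 22 salicylic acid and defence genes 17 were lower in set 2 (median -0.57, adjusted p = 2.52e-07; adjusted p = 0.569 with an estimated correlation), among them SARD1 at 130 and 15.4 in the wild type and 90.9 and 15.9 in the transgenic line.

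Genes of abscisic acid, cold and drought responses were higher in set 2 for 19 of 21 members (median 0.58, adjusted p = 2.52e-07; adjusted p = 0.569 with an estimated correlation). NCED3, an enzyme of abscisic acid synthesis, read 17.3 and 46.9 in the wild type and 9.57 and 44.0 in the transgenic line. Clock genes of the morning list were higher for 7 of 9 members (median 0.56, adjusted p = 0.00244) and those of the evening list for 10 of 12 (median 0.21, adjusted p = 0.022). With an estimated correlation their adjusted p was 0.569 and 0.618. LNK1 read 26.2 and 164 in the wild type and 19.0 and 177 in the transgenic line, and GI read 116 and 331, and 96.3 and 374. LHY was lower in set 2, at 20.01 and 13.6 in the wild type and 18.9 and 11.1 in the transgenic line, whereas CCA1 was higher, at 10.3 and 16.3, and 14.4 and 19.7. Heat shock genes (adjusted p = 0.00144), iron genes (0.0195) and light and elongation genes (0.0246) were the other lists called, all higher in set 2, and each had an adjusted p of 0.569 with an estimated correlation. Only 4 genes were called between the sets over all genes, and 1679 of 18081 were called among genes above the valley, 921 higher and 758 lower.

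The difference between the sets was weighed against 3 technical explanations, and the design names no biological group that goes with the replicate number, so no biological explanation was tested. Normalization between arrays is argued against as the whole cause only so far as it moves genes of one level alike. The jasmonate and salicylic acid genes differed from the abscisic acid gene of the nearest level by a median of -1.54 on the log2 scale, with 39 of 42 gaps below 0. The sign of these gaps restates the opposite directions already seen, and 17 abscisic acid genes served for all 42. What bears on normalization is that the matched levels were close. Their absolute log2 gap had a median of 0.13 and was at most 0.76. Harvest at another time of day cannot be told apart from other causes: CCA1 and LHY, which peak together at dawn, differed in opposite directions, by a gap of 1.22 on the log2 scale, but both lay near the valley of 12.9, with geometric means of 14.8 and 15.4. Another share of root tissue cannot be told apart from other causes, because the root markers had a median of 0.14, and 5 of the 6 were near background while CASP1 differed by 1.34.

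AT5G24240, AT2G41451 and AT1G50020 went between near background and clear signal with genotype. Noise of single arrays is argued against, as far as arrays vary independently. Jumps of at least 3.06 on 1 array alone occurred 4 times among 32627 genes. That cutoff is the smallest difference of these 3 genes within a set, so it came from the genes themselves. At that frequency, with arrays taken as independent, 6.13e-05 genes would jump on both arrays of a genotype by chance. Loss or gain of a stretch of chromosome that changes several genes by 1 or more on the log2 scale is argued against too for AT2G41451 and AT1G50020. Their immediate neighbours lay above the valley. Among the 11 neighbours of all 3 genes above the valley, up to 3 on each side, the largest absolute log2 difference was 0.57. It belonged to ARP beside AT2G41451, and TUA2 beside AT1G50020 differed by -0.46, both in the direction of the gene they flank. On the other side AT2G41450 and TOR differed by 0.11 and -0.0097. A stretch with a smaller effect on its genes is not addressed. Beside AT5G24240, however, AT5G24220, AT5G24230 and AT5G24250 lay under the valley, so a stretch limited to them is not addressed. The nearest neighbours of AT5G24240 above the valley, AT5G24210 and AT5G24260, differed by 0.30 and -0.06. A sequence or epigenetic difference of the transgenic line other than the transgene's action stays open beside an effect of JMJ30, as untested, because the labels do not tell transgenic lines apart.

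The spread between arrays was larger in one part of the locus order, from AT4G24000 on through chromosome 5. Among dim transcript models the SD of the set-by-genotype contrast went from 0.31 to 0.39, a ratio of 1.27 (95% interval 1.24 to 1.31). The step was placed where the variance of this same contrast of dim models changed most, so a ratio above 1 was built in. The interval leaves that choice out. This part held 28.1% of nuclear genes but 57 of the 106 (53.8%) with an unadjusted p under 0.01, and 13 of the 20 genes with the largest moderated t, 10 per direction. A genotype effect on one part of the genome is argued against as the whole cause by the models above the valley, which did not place the step. Their set-by-genotype contrast, in which the genotype difference cancels, had a ratio of 1.24 (95% interval 1.18 to 1.31). The genotype contrast stepped up as well, by a ratio of 1.24 in dim models and 1.265 in those above the valley. Dimmer signals are argued against, because the median log2 level of these models differed by only 0.024 across the step. Fewer probes behind each value could give the variance ratio of 1.62, but probe counts are not given in the sources used here, so this cannot be told apart from other causes.

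AT4G39345 read 377 on the first transgenic array and 5.597, 9.38 and 9.60 on the other 3. Among the 18081 genes above the valley with the replicate block, FLC had the rank 7 by p (adjusted p = 0.623; 0.825 to 1.0 over its other alternatives).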
